A study of Mus musculus with 11 samples.

How the data were processed

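RNA was measured in 11 libraries of activated mouse CD8+ T cells, 4 treated with recombinant human acyloxyacyl hydrolase (AOAH), 3 with the phosphatidylcholine PC16:0-20:4 (PC) and 4 with vehicle. Per the labels' protocols, polyadenylated RNA was converted with primers that carry random priming sites and unique molecular identifiers, ERCC spike-in RNA was added before library preparation, and paired reads of 150 bp were sequenced on a NovaSeq instrument. The labels number the libraries of each group by batch, 1 to 4, and no PC library has batch 4. Nothing in the labels says that these libraries came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels conflict on timing, because the treatment protocol places AOAH in the pretreatment while the sample descriptions place it in the activation step after ethanol alone. They also name both plate-bound anti-CD3 and beads, and medium with or without interleukin-2, and the groups were used as the labels assign them.

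The authors quantified transcripts with RSEM and deposited 1 table of 25562 gene symbols as log2 values of TPM plus 1, where TPM is a length-corrected share of the transcripts of a library, per the submitters' processing notes and the values themselves. The back-transformed TPM values of the deposited table summed to between 998405 and 998655 per library, and 99.9% of them were whole multiples of 0.01 TPM within a tolerance of 1e-04. The submitters' processing notes name the genome build mm39, and the aligner, the annotation, the use of the molecular identifiers and all versions are not given in the sources used here. Depth per library is unknown, since TPM keeps none. The authors' deposited DESeq2 tables hold a base mean (a signal: counts divided by size factors and averaged over libraries), a log2 fold change with another column for its standard error, a Wald score, a p-value and an adjusted p-value for AOAH and for PC against vehicle. Their base means summed to 23462105 and 23887967 normalized counts per library on average. The authors' deposited repertoire table holds other measures per library, which were clonotype and clone numbers, entropy and clonality per receptor chain, made with MiXCR per the labels, with no visible scaling to depth.

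All gene tests were made on log2(TPM + 1) with limma, with a mean-variance trend and robust variance estimation, two-sided, at a Benjamini-Hochberg adjusted p under 0.05, on genes with a mean of at least 1 TPM over the libraries compared. A fold change on this scale understates the change of low genes. AOAH was compared with all 4 vehicle libraries, PC with vehicle 1 to 3 only, since the label of vehicle 4 does not list the PC comparison, and AOAH with PC directly. Gene lists, 39 in all, were written before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts adjusted over the list alone were made by adjusting the gene p-values within that list. Among the lists written beforehand, no call held with an estimated correlation in any of the 3 comparisons.

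Genes were named by rule: a panel of 14 genes, the 8 largest rises and 8 largest falls among genes past the threshold with at least 5 TPM in the higher group and the same sign in every same-batch pair, and the 4 members of lowest p of each list called. Genes with no symbol of their own were passed over, and results for some genes under the rule are not reported here. The few members that moved against their list, members of lists that were not called, and the genes named only in the closing section were chosen after their values were seen. Mouse gene names come from the tables, and no coordinates are given because the reference at hand was of another build than the deposited tables. That reference gave GC content, transcript length and the symbols of Ensembl IDs, which matched 22521 of 23418 IDs for AOAH and 23450 of 24346 IDs for PC.

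Same-batch libraries of different groups were compared by the correlation, across genes, of their deviations from the group means. It averaged -0.0033 in 10 same-batch pairs (-0.0794 to 0.118) and 0.0011 in 30 different-batch pairs (-0.125 to 0.140), and the pairing was taken from the batch labels. By this measure same-batch libraries were no more alike than others. A fit with batch as a block was run beside each test all the same, because the labels give batches. The other alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, 1 fit over all 11 libraries, TPM rescaled by unweighted TMM factors computed for this work, quantile normalization, rescaling without mitochondrial and receptor segment genes, array weights, vehicle 4 included for PC, and each replicate left out in turn.

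The gene test was tested on simulated data made from the real means and variances, with 50 genes changed at each of 4 sizes. For log2 changes of 0.25, 0.5, 1 and 2 it recovered 28%, 74%, 96% and 96% of 50 genes for AOAH against vehicle, 28%, 50%, 90% and 98% for PC against vehicle, and 42%, 66%, 94% and 98% for AOAH against PC. False calls, counted only among genes left unchanged, numbered 14 for AOAH against vehicle, beside 14, 37, 48 and 48 genes recovered at the 4 sizes. For PC against vehicle they numbered 8, beside 14, 25, 45 and 49 recovered. For AOAH against PC they numbered 10, beside 21, 33, 47 and 49 recovered. The simulated data held 11561, 11628 and 11596 genes, 200 of them changed. Of 20 repertoire measures 14 were tested by exact two-sided permutation of the library labels. The other 6, all of immunoglobulin chains, were left out because they had missing values or names that start with Ig. IGH and IGL measures with complete values were kept, though 5 libraries held 1 or no IGH clonotype and ratios over so few mean little. R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.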

Results

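RNA was measured in CD8+ T cells, the lymphocytes that kill infected and tumour cells, isolated by kit from spleens of C57BL/6 mice, an inbred laboratory strain. The cells were kept for 22 h in a pretreatment and then activated for 24 h with antibodies to CD3 (1 µg/mL) and CD28 (0.5 µg/mL), which stand in for antigen and costimulation. There were 4 AOAH libraries, treated with 10 µg/mL recombinant human AOAH, a lipase best known for removing fatty acyl chains from bacterial lipopolysaccharide and from phospholipids. There were 3 PC libraries, pretreated with 60 µM PC16:0-20:4, a phosphatidylcholine that carries palmitic acid and arachidonic acid. They were then given a protein buffer control with 10% glycerol. The 4 vehicle libraries received ethanol and the same buffer with 10% glycerol. The AOAH libraries are labelled with ethanol too, and no glycerol share is given for them, so a difference in buffer cannot be told apart from AOAH. The labels differ on whether AOAH was present in the pretreatment or in the activation step.

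Between 11423 and 11739 genes per library were at 1 TPM or more, with 11423 to 11497 in AOAH, 11641 to 11739 in PC and 11569 to 11633 in vehicle. The 10 most abundant genes held 7.51% to 8.50% of the TPM, and genes of the mitochondrial genome held 3.39% to 3.62%. Correlations across genes between libraries of 1 group lay between 0.983 and 0.988, and no 2 libraries held identical values. Cd8a stood at 331 to 446 TPM and Cd4 at 0.11 to 0.42 TPM. The mouse Aoah transcript stood at 0 to 0.06 TPM and was not tested, and the recombinant human protein leaves no trace in these values. The depth of each library is unknown, because the tables hold TPM.

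The first comparison asked what AOAH changed in activated CD8+ T cells. Genes of naive and resting T cells and of the interferon response were lower with AOAH, and genes of DNA replication, mitosis and glycolysis were higher. Il7r, the receptor chain for a cytokine that keeps naive T cells alive, stood at 18.0 ± 3.30 TPM with AOAH and 78.6 ± 4.76 TPM with vehicle (SD, n = 4 in each group), a log2 change of -2.08 ± 0.11 (SE, limma adjusted p = 1.76e-05). S1pr1, the receptor that guides T cells out of lymphoid organs, stood at 7.26 ± 0.922 and 30.2 ± 2.83 TPM (log2 change -1.92 ± 0.09, adjusted p = 1.00e-05). Klf2, a transcription factor of resting T cells that drives S1pr1, stood at 11.8 ± 0.981 and 43.4 ± 5.85 TPM (log2 change -1.79 ± 0.10, adjusted p = 1.61e-05). Slc16a3, which exports lactate, rose from 10.5 ± 2.24 to 25.8 ± 1.58 TPM (log2 change 1.24 ± 0.13, adjusted p = 2.41e-04).

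Among the 11561 genes tested, limma called 2913, with 1514 higher and 1399 lower with AOAH, and 4358 had an unadjusted p under 0.05. Changes of at least 2-fold were mostly falls, with 71 genes lower and 6 higher. The other large falls were in Cd7, a T cell surface protein (-1.75, adjusted p = 1.09e-04), Slc28a2b, a nucleoside transporter gene (-1.74), the interferon-inducible genes Ifi213 (-1.66) and Ifit1bl1 (-1.63), and Pou6f1, a transcription factor (-1.49), all as log2 changes. Large rises were found in Ak4, a mitochondrial adenylate kinase (1.12, adjusted p = 0.0146), the histone gene H2ac15 (1.12), Kntc1, a kinetochore protein (0.89), Slc16a10, an aromatic amino acid transporter (0.84), and Slc9b2, a sodium and proton exchanger (0.72). Slc28a2b, Ifi213, Ifit1bl1 and the histone genes have close paralogs, so reads may have been divided among copies. H2bc14, a histone gene (0.81, adjusted p = 0.0465), lost its call with batch as a block (adjusted p = 0.0939), with no filter (0.103), with a pseudocount of 0.1 (0.0567), with array weights (0.0523) and without AOAH 1 (0.104), AOAH 2 (0.0600), AOAH 3 (0.103), AOAH 4 (0.0818), vehicle 1 (0.0758) or vehicle 4 (0.0766). Cln8, an endoplasmic reticulum protein (0.71, adjusted p = 0.0211), lost it with no filter (adjusted p = 0.0535) and without AOAH 2 (0.0558) or AOAH 3 (0.0530).

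Of 30 tested genes of naive, memory and quiescent T cells, 21 fell, 1 rose and 8 did not pass (22 and 2 adjusted over the list alone). The naive and quiescence list had a median log2 change of -0.34, adjusted p = 2.86e-13, and adjusted p = 0.104 with an estimated correlation. Txnip, a brake on glucose uptake, fell by 1.05 on the log2 scale, Pik3ip1, a brake on PI3 kinase, by 1.47, and Tcf7, a transcription factor of naive and memory T cells, by 0.44. The member that rose was Pdlim1 (0.13). In the interferon response list 37 of 41 genes fell and none rose (38 fell adjusted over the list alone). The interferon response list had a median log2 change of -0.48, adjusted p = 8.18e-24, and adjusted p = 0.147 with an estimated correlation. Ifit3 stood at 3.71 ± 0.489 TPM with AOAH and 11.4 ± 0.712 TPM with vehicle (log2 change -1.40), and Gbp6 (-0.57) also fell. The labels name no interferon treatment, and B cell markers, tested as other cells the spleen could give, did not pass as a list (3 of 8 fell, adjusted p = 0.0801, and 0.0417 without AOAH 4). Those that fell were Ighm (-0.18), H2-Aa (-0.60) and H2-Ab1 (-0.66).

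DNA replication and mitosis genes were higher with AOAH. Of 36 S phase genes 34 rose and none fell (35 adjusted over the list alone). The S phase list had a median log2 change of 0.27, adjusted p = 1.32e-17, and adjusted p = 0.256 with an estimated correlation. Tyms, which makes thymidylate for DNA, rose by 0.49, Rrm2, a ribonucleotide reductase subunit, by 0.44, and Uhrf1, which keeps DNA methylation through replication, by 0.31 on the log2 scale. Of 38 G2 and M phase genes 27 rose and none fell (36 adjusted over the list alone). The G2 and M phase list had a median log2 change of 0.34, adjusted p = 2.21e-12, and adjusted p = 0.314 with an estimated correlation. Top2a, a topoisomerase of dividing cells, stood at 191 ± 5.87 TPM with AOAH and 145 ± 12.9 TPM with vehicle, and Ccna2 (0.45), Nuf2 (0.42) and Cks2 (0.33) also rose. Mki67, a proliferation marker, had a log2 change of 0.33, adjusted p = 0.101, and passed without vehicle 1 (0.0454).

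Glycolysis genes rose in 19 of 24 cases with none falling (19 adjusted over the list alone). The glycolysis list had a median log2 change of 0.25, adjusted p = 3.03e-12, and adjusted p = 0.256 with an estimated correlation. Ldha, lactate dehydrogenase, stood at 2236 ± 19.8 TPM with AOAH and 1751 ± 32.2 TPM with vehicle, and Tpi1 (0.51), Pgk1 (0.26) and Pkm (0.25) rose as well. MYC and ribosome biogenesis genes rose in 31 of 40 cases with none falling (33 adjusted over the list alone). The MYC and ribosome biogenesis list had a median log2 change of 0.17, adjusted p = 4.37e-14, and adjusted p = 0.104 with an estimated correlation. Odc1 (0.27), the first enzyme of polyamine synthesis, and the nucleolar genes Npm1 (0.17) and Nop56 (0.16) were examples. Ribosomal protein genes went the other way, with 19 of 40 lower and none higher (28 adjusted over the list alone), but 7 lower under TMM rescaling and 11 lower with 1 higher under quantile normalization, which kept the direction of the median. The ribosomal protein list had a median log2 change of -0.08, adjusted p = 8.99e-10, and adjusted p = 0.314 with an estimated correlation. Rps27 (-0.29) and Rps15 (-0.14) were examples. Heat shock genes rose in 10 of 14 cases (11 adjusted over the list alone), among them Hspd1 (0.23). The heat shock list had a median log2 change of 0.14, adjusted p = 4.79e-06, and adjusted p = 0.25 with an estimated correlation. The tricarboxylic acid cycle list had 6 of 20 genes higher and none lower (6 adjusted over the list alone), among them Idh3a (0.19) and Dlat (0.22). The tricarboxylic acid cycle list had a median log2 change of 0.08, adjusted p = 0.0489, and adjusted p = 0.314 with an estimated correlation. Under quantile normalization 2 of its genes were higher and 3 lower, with a median of 0.0268. The list call was lost with batch as a block (adjusted p = 0.0708) and without AOAH 1 (0.0674), AOAH 3 (0.0555), vehicle 1 (0.0640), vehicle 3 (0.0527) or vehicle 4 (0.0918).

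Signalling genes moved in both directions with AOAH. Early T cell activation genes rose in 15 of 30 cases and fell in 1, Jun (-0.28), with 17 and 1 adjusted over the list alone. The early activation list had a median log2 change of 0.15, adjusted p = 2.31e-05, and adjusted p = 0.314 with an estimated correlation. Tfrc, the transferrin receptor, stood at 214 ± 3.55 TPM with AOAH and 148 ± 17.1 TPM with vehicle, and Tnfrsf4, the costimulatory receptor OX40, rose by 0.47 on the log2 scale. Proximal T cell receptor signalling genes fell in 12 of 32 cases and rose in 6 (13 and 6 adjusted over the list alone). The receptor signalling list had a median log2 change of -0.06, adjusted p = 0.0133, and adjusted p = 0.314 with an estimated correlation. Under quantile normalization 15 of its genes fell and 5 rose, with a median of -0.0979. Rasgrp1 (-0.47), Prkcq (-0.37) and Cd8b1 (-0.27), a chain of the CD8 coreceptor, fell, while Ptpn6, a phosphatase that dampens receptor signals, rose (0.24). Interleukin-2 and STAT5 targets fell in 10 of 20 cases and rose in 3, Il2ra, Lif and Ccnd2 (10 and 4 adjusted over the list alone). The STAT5 list had a median log2 change of -0.10, adjusted p = 0.0131, and adjusted p = 0.314 with an estimated correlation. Socs3 (-0.72), Socs1 (-0.52), feedback inhibitors of cytokine signals, and the survival gene Bcl2 (-0.34) were among those that fell. Liver X receptor targets and cholesterol export genes fell in 6 of 11 cases with none rising (7 lower and 1 higher adjusted over the list alone). The Liver X receptor list had a median log2 change of -0.29, adjusted p = 6.33e-04, and adjusted p = 0.25 with an estimated correlation. Examples were Arl4c (-1.06), Mylip (-0.96) and Npc2 (-0.29). Endoplasmic reticulum stress and ATF4 targets rose in 13 of 32 cases and fell in 4 (16 and 5 adjusted over the list alone). The ATF4 list had a median log2 change of 0.10, adjusted p = 0.0216, and adjusted p = 0.314 with an estimated correlation. Under quantile normalization 9 of its genes rose and 4 fell, with a median of 0.0536. The chaperone Hsp90b1 (0.19) rose, whereas Ddit3 (-0.44), Trib3 (-0.36), Herpud1 (-0.15) and Edem1 (-0.18) fell.

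Cytotoxic effector genes were not called as a list with AOAH, with 7 of 23 higher and 7 lower (adjusted p = 0.686), nor were cytokine and chemokine genes (5 of 21 higher, 4 lower, adjusted p = 0.591) or inhibitory receptor genes (7 of 23 higher, 5 lower, adjusted p = 0.824). The cytokine genes that rose were Ccl3 (0.38), Lif (0.37), Tnfsf9 (0.28), Xcl1 (0.13) and Ccl4 (0.12), and those that fell were Ccl5 (-0.92), Ltb (-0.55), Cxcl10 (-0.28) and Osm (-0.20). The inhibitory genes that fell were Cd101 (-0.70), Nt5e (-0.65), Dgka (-0.55), Vsir (-0.33) and Il10ra (-0.30). Prf1, perforin, rose from 99.8 ± 7.64 to 126 ± 3.80 TPM (log2 change 0.34 ± 0.05, adjusted p = 0.00214), and Pdcd1, the inhibitory receptor PD-1, rose from 55.0 ± 5.82 to 76.2 ± 1.36 TPM (log2 change 0.47 ± 0.07, adjusted p = 0.00127). Ifng had a log2 change of -0.01, adjusted p = 0.959, Gzmb, granzyme B, -0.04, adjusted p = 0.192, Tnf 0.04, adjusted p = 0.756, Il2 0.16, adjusted p = 0.291, Nr4a1 0.08, adjusted p = 0.129, and Myc 0.06, adjusted p = 0.0688. Cd69 (0.11, adjusted p = 0.011) and Il2ra (0.14, adjusted p = 0.0185) rose slightly. Cd69 lost its call with 1 fit over all 11 libraries (adjusted p = 0.0950) and with quantile normalization (0.0807), and Il2ra with quantile normalization (0.0712), with batch as a block (0.0645) and without AOAH 4 (0.0534) or vehicle 2 (0.0541). Long noncoding RNAs, which can move with RNA quality, were not called (2 of 6 fell, adjusted p = 0.113), and those that fell, chosen after their values were seen, were Neat1 (-1.14) and Malat1 (-0.69). The authors' deposited table called 2139 genes for this comparison, 1055 higher and 1084 lower, and of 2038 of them among the 11032 genes matched here, 1859 (91.2%) were called here, all in the same direction.

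**Figure D1:**
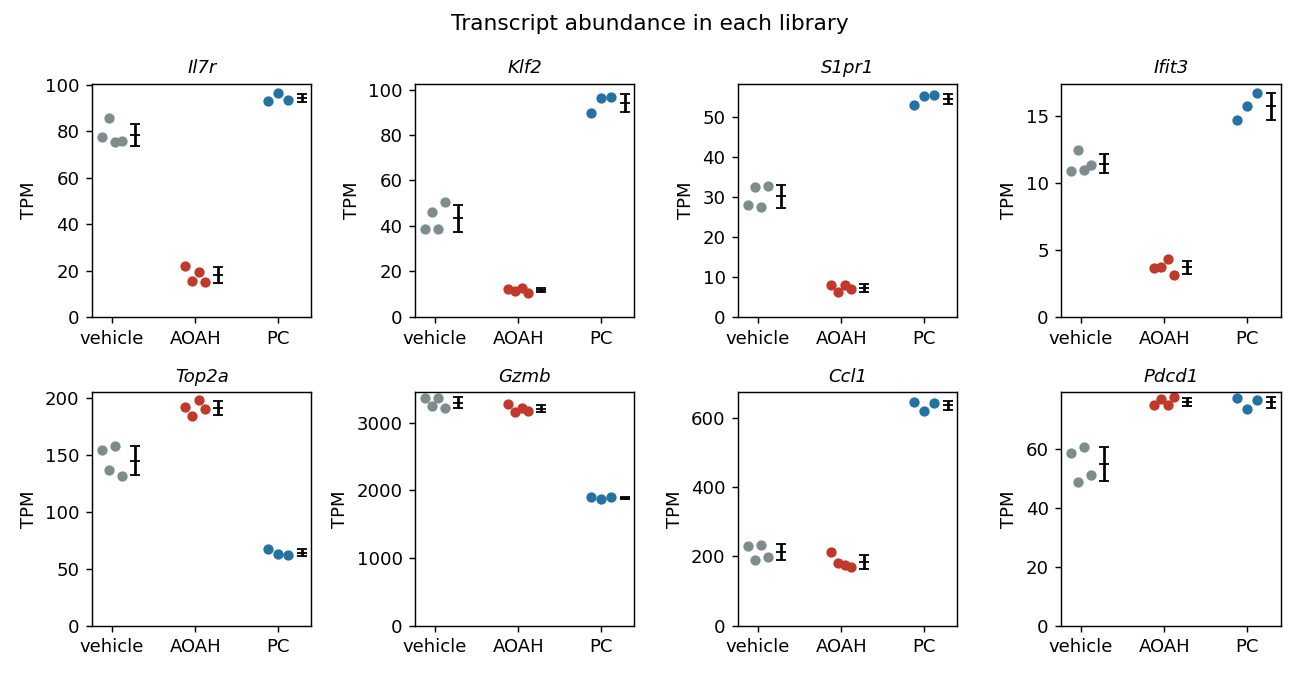
TPM of 8 genes in each of the 11 libraries (points), with the mean and SD of each group (AOAH n = 4, PC n = 3, vehicle n = 4). Il7r, Klf2, S1pr1 and Ifit3 lie lowest in the AOAH libraries, Top2a and Gzmb lowest in the PC libraries, Ccl1 highest in the PC libraries, and Pdcd1 higher in both treated groups than in vehicle.

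The comparison of PC with vehicle 1 to 3 asked what loading with the arachidonoyl phosphatidylcholine before activation changed. Cell division genes were lower with PC, while chemokine genes and genes of naive T cells were higher. Also higher were a mixed list of endoplasmic reticulum stress genes and ATF4 targets, and targets of the stress regulator NRF2. Mki67 stood at 8.85 ± 0.345 TPM with PC and 28.6 ± 4.96 TPM with vehicle (SD, n = 3 in each group), a log2 change of -1.57 ± 0.12 (SE, limma adjusted p = 8.15e-04). Gzmb, a granule protease that kills target cells, stood at 1890.1 ± 18.1 and 3324 ± 64.2 TPM (log2 change -0.81 ± 0.02, adjusted p = 8.50e-06). Ccl1, a chemokine of activated T cells, rose from 218 ± 25.4 to 637 ± 13.6 TPM (log2 change 1.55 ± 0.08, adjusted p = 4.62e-04), and Klf2 rose from 41.1 ± 4.29 to 94.2 ± 4.02 TPM (log2 change 1.18 ± 0.07, adjusted p = 6.84e-04).

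Of 11628 genes tested, limma called 2270, with 962 higher and 1308 lower with PC, 16 of them at least 2-fold higher and 65 at least 2-fold lower, and 3909 had an unadjusted p under 0.05. The count was 1405 without PC 2, 1387 without PC 3, 1274 without vehicle 1, 1391 without vehicle 3, 1339 with no expression filter, and 1572 with batch as a block. Under the naming rule the largest falls besides Mki67 were in Drc1, a ciliary dynein regulator (-1.75, adjusted p = 0.00408), and in the mitotic genes Ube2c (-1.66), Plk1 (-1.49), Ccnb1 (-1.43), Hmmr (-1.42) and Cdca3 (-1.37), all as log2 changes. The histone gene H2ac24 stood at 716 ± 21.9 TPM with PC and 2002 ± 66.6 TPM with vehicle, and has close paralogs. Besides Ccl1 and Klf2, the largest rises under that rule were in the receptor segment Trav12-1 (1.13), which has close paralogs, AA467197 (1.12), Derl3, which helps remove misfolded proteins from the endoplasmic reticulum (1.10), Il23a, a subunit of interleukin-23 (1.10), Hmox1, heme oxygenase (1.01), and Trib3, a pseudokinase induced by ATF4 (1.00). Gm13192, which the rule passed over for want of a symbol of its own, rose by 5.14 on the log2 scale (limma adjusted p = 1.18e-05). It stood at 34.8 TPM with PC and at a mean of 4.25 TPM over all 4 vehicle libraries. The size of this change therefore rests on leaving out vehicle 4. Gm13192 rose with AOAH too, against all 4 vehicle libraries (log2 change 4.11 ± 0.996, SE, limma adjusted p = 0.0220).

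Of 38 G2 and M phase genes 36 fell with PC and none rose (36 adjusted over the list alone). The G2 and M phase list had a median log2 change of -1.04, adjusted p = 4.27e-24, and adjusted p = 0.204 with an estimated correlation. Top2a stood at 64.2 ± 3.07 TPM with PC and 149.7 ± 11.3 TPM with vehicle, and Birc5, which is needed for chromosome segregation, fell by 1.27 on the log2 scale. All 36 S phase genes fell (36 adjusted over the list alone), among them Rrm2 (-1.01), the E2F family repressor E2f8 (-1.16), cyclin E1, Ccne1 (-0.56), and Fen1 (-0.49). The S phase list had a median log2 change of -0.47, adjusted p = 3.75e-23, and adjusted p = 0.204 with an estimated correlation. Glycolysis genes fell in 12 of 24 cases with none rising (14 adjusted over the list alone), among them Tpi1 (-0.40), Eno1 (-0.22) and Pdk1 (-0.39). The glycolysis list had a median log2 change of -0.16, adjusted p = 4.41e-05, and adjusted p = 0.271 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 8 of 40 cases with none rising (8 adjusted over the list alone), among them Atp5a1 (-0.16) and Sdhd (-0.24). The oxidative phosphorylation list had a median log2 change of -0.06, adjusted p = 0.00239, and adjusted p = 0.204 with an estimated correlation. Tricarboxylic acid cycle genes fell in 8 of 20 cases with none rising (8 lower and 1 higher adjusted over the list alone), among them Suclg2 (-0.44) and Idh3a (-0.17). The tricarboxylic acid cycle list had a median log2 change of -0.08, adjusted p = 0.00239, and adjusted p = 0.204 with an estimated correlation. MYC and ribosome biogenesis genes fell in 9 of 40 cases with none rising (9 adjusted over the list alone), among them Ncl (-0.19) and Polr1a (-0.28). The MYC and ribosome biogenesis list had a median log2 change of -0.08, adjusted p = 0.00124, and adjusted p = 0.204 with an estimated correlation, and 5 of its genes fell under TMM rescaling. Ribosomal protein genes were higher in 10 of 40 cases with none lower (10 adjusted over the list alone), 6 under TMM rescaling and 8 under quantile normalization, among them Rps16 (0.11). The ribosomal protein list had a median log2 change of 0.04, adjusted p = 1.71e-05, and adjusted p = 0.429 with an estimated correlation.

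Genes of naive, memory and quiescent T cells rose in 19 of 30 cases with PC and fell in 1, Ly6c2 (-0.24), with 20 and 1 adjusted over the list alone. The naive and quiescence list had a median log2 change of 0.33, adjusted p = 3.60e-10, and adjusted p = 0.204 with an estimated correlation. S1pr1 rose by 0.88, Cd27, a costimulatory receptor, by 0.45, Tcf7 by 0.31 and Il7r by 0.25 on the log2 scale. Proximal T cell receptor signalling genes rose in 18 of 32 cases and fell in 1, Cd28 (-0.23), with 19 and 1 adjusted over the list alone. The receptor signalling list had a median log2 change of 0.14, adjusted p = 6.66e-09, and adjusted p = 0.204 with an estimated correlation. Zap70 (0.37), the kinase next to the receptor, its receptor chain Cd247 (0.32) and the phosphatase Ptpn22 (0.35) were examples. Cytokine and chemokine genes rose in 8 of 22 cases and fell in 2, Lif (-0.33) and Osm (-0.30), with 10 and 3 adjusted over the list alone. The cytokine list had a median log2 change of 0.07, adjusted p = 0.0035, and adjusted p = 0.271 with an estimated correlation. Lif lost its call with vehicle 4 included (adjusted p = 0.135) and with 1 fit over all 11 libraries (0.116). Xcl1, a chemokine that attracts dendritic cells, stood at 4035 ± 114 TPM with PC and 2849.7 ± 109 TPM with vehicle, and Ccl4 (0.44) and Ccl9 (0.57) rose as well. Inhibitory receptor genes rose in 8 of 23 cases and fell in 1, Il10ra (-0.40), with 9 and 1 adjusted over the list alone. The inhibitory receptor list had a median log2 change of 0.14, adjusted p = 0.00285, and adjusted p = 0.206 with an estimated correlation. Vsir, the checkpoint receptor VISTA (0.78), Lag3 (0.57) and Pdcd1 (0.43), both inhibitory receptors, rose.

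Stress and lipid genes changed with PC as well. Endoplasmic reticulum stress and ATF4 targets rose in 19 of 32 cases and fell in 2, Psat1 (-0.16) and Phgdh (-0.20), enzymes of serine synthesis, with 20 and 3 adjusted over the list alone. The ATF4 list had a median log2 change of 0.23, adjusted p = 1.03e-08, and adjusted p = 0.204 with an estimated correlation. Hspa5, the main chaperone of the endoplasmic reticulum (0.25), Manf (0.31) and Sesn2 (0.70) were higher. NRF2 oxidative stress targets rose in 12 of 25 cases and fell in 2, Gpx4 (-0.16) and Tkt (-0.16), with 12 and 4 adjusted over the list alone. The NRF2 list had a median log2 change of 0.08, adjusted p = 0.00187, and adjusted p = 0.204 with an estimated correlation. Sqstm1, an autophagy receptor (0.65), Esd (0.39) and the ferritin light chain Ftl1 (0.33), which has pseudogene copies, were examples. Genes of the cyclic AMP and prostaglandin E2 response rose in 10 of 19 cases with none falling (10 adjusted over the list alone), among them Rgs2 (0.61), Rgs16 (0.54), the phosphodiesterase Pde4b (0.53) and Crem (0.43). The cyclic AMP list had a median log2 change of 0.19, adjusted p = 6.78e-05, and adjusted p = 0.271 with an estimated correlation. Fatty acid oxidation and PPAR targets fell in 8 of 25 cases and rose in 3, Cpt1a (0.31), Acadm (0.31) and Acadvl (0.16), all 3 enzymes of fatty acid oxidation, with 13 and 5 adjusted over the list alone. The calls of Cpt1a (adjusted p = 0.0607), Acadm (0.0847) and Acadvl (0.0991) ended with batch as a block. The fatty acid oxidation list had a median log2 change of -0.13, adjusted p = 0.0348, and adjusted p = 0.271 with an estimated correlation, and 5 of its genes fell and 2 rose under TMM rescaling. It lost its call without vehicle 1 (adjusted p = 0.0562) or vehicle 2 (0.0664). The fatty acid carrier Fabp5 (-0.64), the lipid droplet protein Plin2 (-0.54) and Hadh (-0.38) fell. Fatty acid synthesis genes fell in 3 of 15 cases with none rising (6 adjusted over the list alone). The fatty acid synthesis list had a median log2 change of -0.14, adjusted p = 0.0206, and adjusted p = 0.271 with an estimated correlation. The 3 that fell were Scd2 (-0.71), a fatty acid desaturase, Acsl1 (-0.47) and Acaca (-0.47). Acsl1 lost its call with batch as a block (adjusted p = 0.0632) and without PC 1 (0.0505), PC 2 (0.0619) or vehicle 1 (0.0541), and Acaca with the block (0.0778) and without PC 1 (0.0699), PC 3 (0.0656), vehicle 1 (0.0867) or vehicle 3 (0.0831).

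Smaller groups were called with PC too. Interleukin-2 and STAT5 targets fell in 9 of 20 cases and rose in 1, Gadd45b (0.20), with 10 and 2 adjusted over the list alone. The STAT5 list had a median log2 change of -0.11, adjusted p = 0.00544, and adjusted p = 0.271 with an estimated correlation. Socs2 (-0.70) and Cdk6 (-0.67) were among those that fell. NF-kB targets rose in 5 of 24 cases, Rel (0.24), Cflar (0.25), Slfn2 (0.20), Bcl2a1d (0.30) and Bcl2a1b (0.22), the last of a family of near-identical copies, and fell in 1, Icam1 (-0.19), with 5 and 1 adjusted over the list alone. The NF-kB list had a median log2 change of 0.11, adjusted p = 0.00503, and adjusted p = 0.271 with an estimated correlation. Icam1 lost its call without vehicle 1 (adjusted p = 0.0565) or vehicle 3 (0.0552), and Bcl2a1b without PC 1 (0.101), PC 2 (0.0932), PC 3 (0.0910) or vehicle 3 (0.0940). Heat shock genes fell in 5 of 14 cases with none rising (7 adjusted over the list alone), and they were Ahsa1 (-0.21), Hsp90aa1 (-0.20), Hspd1 (-0.14), Hspa4 (-0.12) and Stip1 (-0.09). Under quantile normalization Hsp90aa1 (-0.0761, adjusted p = 0.141) and Hspd1 (-0.0685, adjusted p = 0.0713) lost their calls. Stip1 lost its call with batch as a block (adjusted p = 0.0795), with TMM rescaling (0.155), with no filter (0.0775) and without PC 1 (0.0899), PC 2 (0.0999), PC 3 (0.0881), vehicle 1 (0.116) or vehicle 2 (0.0726). The heat shock list had a median log2 change of -0.05, adjusted p = 0.0248, and adjusted p = 0.204 with an estimated correlation. It lost its call with TMM rescaling (adjusted p = 0.0840) and without vehicle 2 (0.0638). The lipopolysaccharide response list had 2 of 12 genes higher, Il1a (0.53) and Tnf (0.44), and none lower (2 adjusted over the list alone). The lipopolysaccharide list had a median log2 change of 0.09, adjusted p = 0.0458, and adjusted p = 0.271 with an estimated correlation. It lost its call without PC 2 (adjusted p = 0.0845) or PC 3 (0.0593), and Il1a lost its own with batch as a block (0.0607) and without PC 1 (0.0619), PC 2 (0.0625) or vehicle 1 (0.0594). Long noncoding RNAs rose in 4 of 6 cases with none falling (5 adjusted over the list alone), Neat1, Malat1, Gas5 (0.18) and Norad (0.16). The noncoding RNA list had a median log2 change of 0.17, adjusted p = 0.0026, and adjusted p = 0.271 with an estimated correlation. Neat1 stood at 72.6 ± 6.79 TPM with PC and 40.1 ± 0.96 TPM with vehicle, beside the rises listed for the stress genes, and Malat1 (0.53) lost its call without PC 3 (adjusted p = 0.0537), vehicle 1 (0.0547) or vehicle 3 (0.0506). Gas5 lost its call without PC 3 (adjusted p = 0.0559) or vehicle 1 (0.0571), and Norad with batch as a block (0.0868) and without PC 2 (0.0932), PC 3 (0.0784), vehicle 1 (0.0660), vehicle 2 (0.0691) or vehicle 3 (0.0769).

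The interferon response list was not called with PC, with 8 of 42 higher and 9 lower (adjusted p = 0.808), nor were cytotoxic effector genes (4 of 23 higher, 7 lower, adjusted p = 0.286). The effector genes that rose were Klrc1 (0.67), Srgn (0.55), Klrd1 (0.32) and Ctsw (0.13), and besides Gzmb the transcription factors Id2 (-0.45), Tbx21 (-0.31) and Eomes (-0.29) were among those that fell. Early T cell activation genes missed the threshold (11 of 30 higher, 5 lower, adjusted p = 0.0506) and were called without PC 1 (0.0228), vehicle 1 (0.0303) or vehicle 3 (0.0384) and under TMM rescaling (0.0491). The early activation genes that fell were Icos (-0.33), Tfrc (-0.29), Il2ra (-0.22), Junb (-0.11) and Myc (-0.10). Of the panel of activation genes, Tnf rose from 117 ± 6.83 to 159 ± 5.77 TPM (adjusted p = 0.00219) and Il2ra fell by 0.22 on the log2 scale (adjusted p = 0.00921). Il2 rose (0.59, adjusted p = 0.0185) and lost its call with batch as a block (adjusted p = 0.0599) and without PC 2 (0.0600) or PC 3 (0.0575). Nr4a1 (0.20, adjusted p = 0.0303) lost its call with the block (adjusted p = 0.0640) and without PC 2 (0.0842), PC 3 (0.0953), vehicle 1 (0.0736), vehicle 2 (0.0802) or vehicle 3 (0.0752). Myc (-0.10, adjusted p = 0.0435) lost its call with the block (adjusted p = 0.0786) and without PC 1 (0.0992), PC 3 (0.0941), vehicle 1 (0.120), vehicle 2 (0.0879) or vehicle 3 (0.0945). Ifng had a log2 change of -0.04, adjusted p = 0.785, Prf1 0.08, adjusted p = 0.309, and Cd69 0.02, adjusted p = 0.862. The authors' deposited table called 1488 genes for this comparison, 638 higher and 850 lower, and of 1447 of them among the 11091 genes matched here, 1323 (91.4%) were called here, all in the same direction.

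Set against each other, AOAH and PC differed most in genes of resting T cells, which were lower with AOAH, and in cell division genes, which were higher with AOAH. Klf2 stood at 11.8 ± 0.981 TPM with AOAH (SD, n = 4) and 94.2 ± 4.02 TPM with PC (SD, n = 3), a log2 difference of -2.90 ± 0.07 (SE, limma adjusted p = 5.25e-07). Mki67 stood at 33.2 ± 2.00 and 8.85 ± 0.345 TPM (log2 difference 1.80 ± 0.06, adjusted p = 1.34e-06), and Gzmb differed by 0.76 ± 0.02 (adjusted p = 5.25e-07). Of 11596 genes tested, limma called 5307, with 2814 higher and 2493 lower with AOAH, 151 of them at least 2-fold higher and 197 at least 2-fold lower, and 6120 had an unadjusted p under 0.05.

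Genes far lower with AOAH than with PC were S1pr1 (-2.76), Il7r (-2.34), Ypel3 (-2.21), the chemokine receptor Cxcr4 (-2.20), Tsc22d3, a gene induced by glucocorticoids (-2.15), Slc28a2b (-2.11) and Pik3ip1 (-2.04), as log2 differences. Genes far higher were Ube2c (1.88), H2ac24 (1.85), Nusap1 (1.79), Plk1 (1.76), Ccnb1 (1.72) and Ak4 (1.71). The histone gene H4c12 (1.85, adjusted p = 0.0216) lost its call without AOAH 4 (0.0570) or PC 3 (0.0567), and with 1 fit over all 11 libraries (0.122). Tcf7 (-0.74), Tnf (-0.43) and Il2 (-0.50) were lower with AOAH, while Il2ra (0.33), Prf1 (0.21) and Myc (0.16) were higher. The differences were 0.00, adjusted p = 0.939 for Pdcd1, -0.01, adjusted p = 0.833 for Ifng, 0.10, adjusted p = 0.192 for Cd69, and -0.13, adjusted p = 0.0763 for Nr4a1, and Nr4a1 passed without AOAH 3 (0.0450) or PC 1 (0.0208), with 1 fit over all 11 libraries (0.0405) and with quantile normalization (-0.1963, adjusted p = 0.0144). Ifng passed with quantile normalization (-0.1083, adjusted p = 0.0424).

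Higher with AOAH than with PC were 36 of 36 S phase genes (median log2 difference 0.66, adjusted p = 1.08e-21) and 37 of 38 G2 and M phase genes (1.30, adjusted p = 1.72e-22), with none lower, among them Rrm2 (1.41), E2f8 (1.65), Top2a (1.56) and the mitotic motor Kif11 (1.65). So were 21 of 24 glycolysis genes, among them Tpi1 (0.89) and Ldha (0.44), 34 of 40 MYC and ribosome biogenesis genes (adjusted p = 6.45e-11) with 1 lower, Polr1c, 19 of 40 oxidative phosphorylation genes with 1 lower, Ndufa2 (12 higher and 5 lower under quantile normalization), and 12 of 20 tricarboxylic acid cycle genes (adjusted p = 8.60e-04) with none lower (9 higher and 1 lower under quantile normalization). Adjusted over the list alone, 36 S phase, 37 G2 and M phase, 21 glycolysis, 35 MYC, 19 oxidative phosphorylation and 15 tricarboxylic acid cycle genes were higher, and 2 of the last were lower. Fatty acid synthesis genes were higher in 11 of 16 cases (11 adjusted over the list alone) and lower in 1, Lpin1 (-0.79), and heat shock genes were higher in 10 of 14 cases (10 adjusted over the list alone) and lower in 1, Dnajb1 (-0.13). With an estimated correlation these 8 lists had adjusted p = 0.0844 at the lowest and adjusted p = 0.188 at the highest.

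Lower with AOAH than with PC were 24 of 30 genes of naive, memory and quiescent T cells with 1 higher, Ly6c2 (0.23; median -0.62, adjusted p = 2.57e-12), and 32 of 41 interferon response genes with none higher (median -0.43, adjusted p = 7.20e-12), among them Ifit3 (-1.83), Rtp4 (-1.61), Irf9 (-0.97) and Cd274, the ligand of PD-1 (-0.74). Cytokine and chemokine genes were lower in 12 of 20 cases, among them Ccl1 (-1.79) and Ltb (-0.56), and higher in 1, Lif (0.60), with adjusted p = 0.00128. Proximal T cell receptor signalling genes were lower in 22 of 32 cases, among them Prkcq (-0.56), Cd247 (-0.54) and Cd8a (-0.37), and higher in 1, Cd28 (0.22), with adjusted p = 1.15e-06. Ribosomal protein genes were lower in 32 of 40 cases, 24 under TMM rescaling and 18 under quantile normalization, among them Rps27 (-0.37), and Liver X receptor targets in 7 of 11, among them Arl4c (-1.41). Stress and ATF4 targets were lower in 18 of 32 cases, among them Trib3 (-1.30) and Ddit3 (-1.10). They were higher in 7, among them Mthfd2 and Phgdh. Long noncoding RNAs were lower in 4 of 6 cases, Neat1 (-1.99), Malat1 (-1.22), Gas5 (-0.28) and Norad (-0.12), and Norad lost its call without PC 2 (adjusted p = 0.0551). NF-kB targets were lower in 13 of 24 cases and higher in 3, Tnfaip8, Icam1 and Bcl2a1b (adjusted p = 0.0425), a call lost without AOAH 3 (0.0511) or PC 3 (0.0558). Under TMM rescaling 14 of these targets were lower and 6 higher. Adjusted over the list alone, 25 naive, 34 interferon, 12 cytokine, 23 receptor signalling, 37 ribosomal protein, 8 Liver X receptor, 20 stress, 15 NF-kB and 4 noncoding RNA genes were lower, and with an estimated correlation these 9 lists had adjusted p = 0.0844 at the lowest and adjusted p = 0.245 at the highest.

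**Figure D2:**
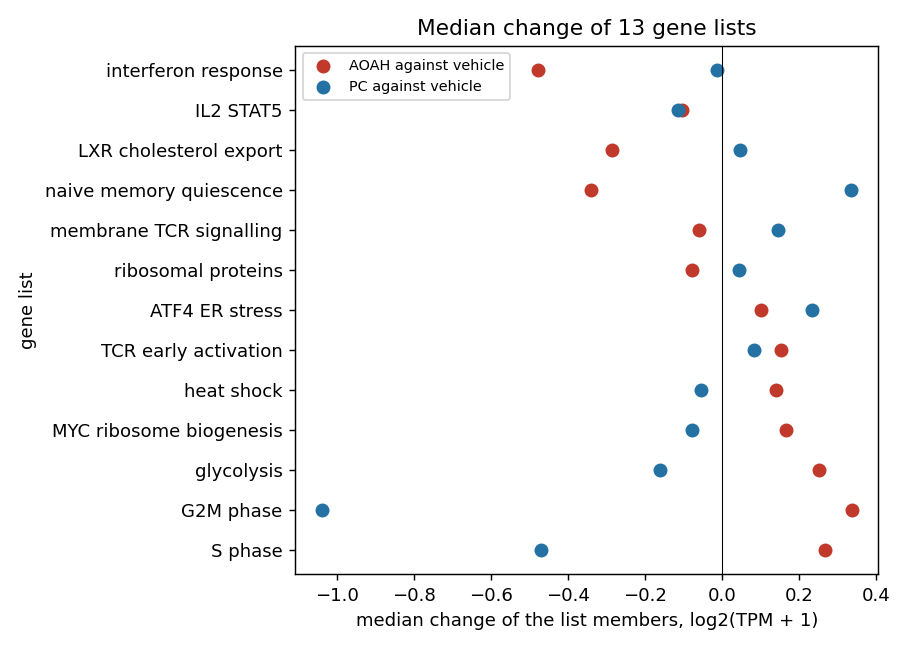
Median log2 change against vehicle of the tested members of 13 gene lists with AOAH (n = 4 against 4 libraries) and with PC (n = 3 against 3). The 13 are the lists called for AOAH except the tricarboxylic acid cycle, so lists called only with PC are not shown. S phase and G2 and M phase lie above 0 with AOAH and below 0 with PC, naive and quiescent genes the other way, and the interferon response is at -0.48 with AOAH and near 0 with PC, where its sign turned under 2 other scalings.

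Genes that responded to both treatments mostly responded in opposite directions. Of 1099 genes called against vehicle in both comparisons, 913 (83.1%) moved oppositely, 560 of them higher with AOAH and lower with PC and 353 lower with AOAH and higher with PC. Cell division genes such as Top2a, Rrm2 and Ccnb1 lie in the first group, and Klf2, S1pr1, Il7r and Tcf7 in the other. Independent lists of these sizes would share 289 genes with opposite direction and 286 with the same direction, where 186 were seen. Both comparisons use the same vehicle libraries, which by itself gives a positive relation: in 100 simulations of unchanged groups the correlation of log2 changes across genes averaged 0.431 (0.307 to 0.547), and 64.2% of genes had the same sign. Across the 11403 genes tested in both, which are not independent replicates, the correlation was -0.0692, the share of equal sign was 40.2%, and the covariance was -0.0054 against a simulated 0.0134, a difference of -0.0188. With the vehicle libraries divided so that each treatment had its own, the correlation lay between -0.279 and -0.165 in 6 divisions, and the genes called in both that moved oppositely numbered from 382 of 476, the lowest share, to 943 of 1068, the highest. The correlation turned positive without vehicle 1 (0.0068) or vehicle 4 (0.0178), alternatives chosen after seeing the data, and with batch as a block 640 of 764 genes called in both moved oppositely.

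**Figure D3:**
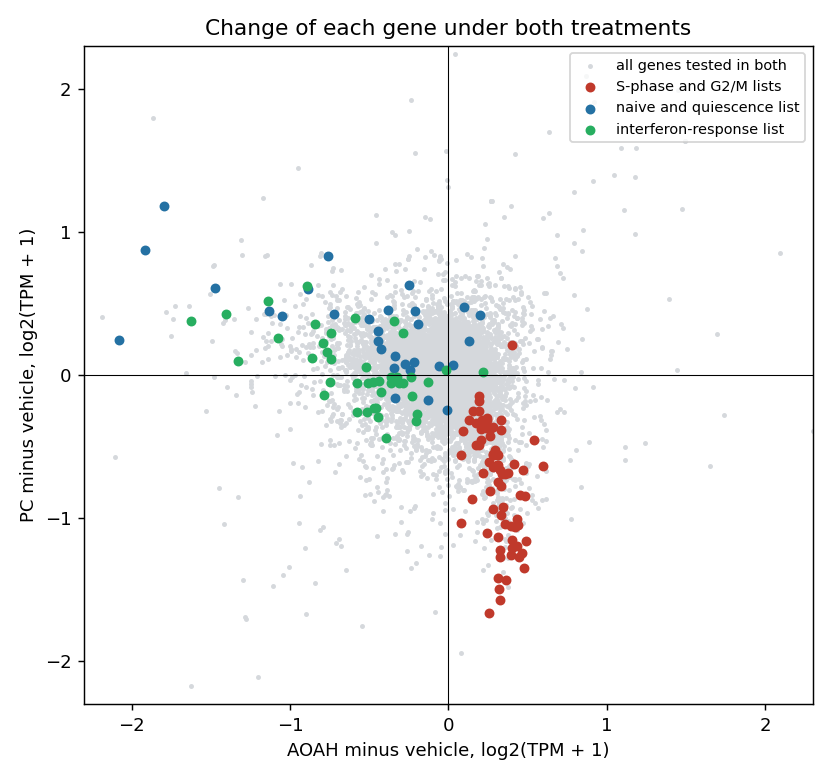
Log2 change with AOAH (horizontal) against log2 change with PC (vertical) for the 11403 genes tested in both, 14 of which lie beyond the axes. S phase and G2 and M phase genes (red) mostly lie to the right and below 0, naive and quiescent genes (blue) mostly to the left and above 0, and interferon response genes (green) to the left and near 0 with PC, where their median changed sign under 2 other scalings.

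T cell receptor clonotypes, distinct receptor sequences assembled from the RNA reads, were more numerous with PC. In PC libraries 1577 ± 54.9 alpha chain (TRA) clonotypes were listed (SD, n = 3), against 1069 ± 67.7 in vehicle 1 to 3, a ratio of 1.47 with the PC library higher in 3 of 3 same-batch pairs. The beta chain (TRB) gave 2868 ± 121 with PC and 2173 ± 135 with vehicle 1 to 3 (SD, n = 3), a ratio of 1.32, also higher in 3 of 3 pairs. For each chain the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give (adjusted p = 0.233 over 14 measures), and with vehicle 4 included the differences were 459 and 576 clonotypes. With AOAH 1094 ± 37.3 TRA clonotypes were listed against 1118 ± 112 in vehicle (SD, n = 4 in each group; exact permutation p = 0.714), and the difference of -24.25 turned to 24.5 without vehicle 4. TRB clonotypes numbered 2024 ± 116 with AOAH and 2292 ± 263 with vehicle (exact permutation p = 0.0857, adjusted p = 0.24), higher in 1 of 4 pairs. The TRB difference of -268 was -149 without vehicle 4 and -360 without vehicle 3. Immunoglobulin light chain (IGL) clonotypes, a mark of B cells, numbered 2.50 ± 1.00 with AOAH and 5.25 ± 1.26 with vehicle (exact permutation p = 0.0571, adjusted p = 0.24), higher in 0 of 4 pairs. RNA of the receptor constant region Trac stood at 355 ± 9.17 TPM with PC, 268 ± 8.34 TPM with AOAH and 267 ± 7.93 TPM with vehicle, and the summed Trbc genes at 1114 ± 20.7, 886 ± 26.4 and 945 ± 23.5 TPM.

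**Figure D4:**
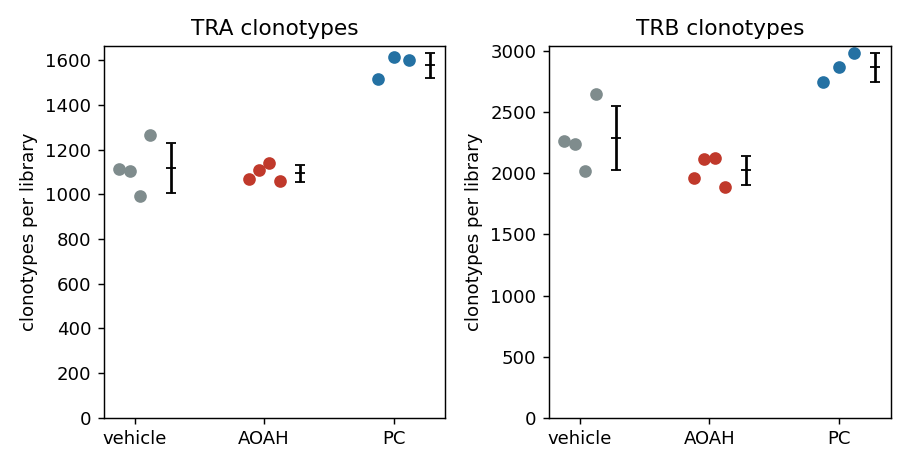
Number of TRA and TRB clonotypes in each library (points), with the mean and SD of each group (AOAH n = 4, PC n = 3, vehicle n = 4). The 3 PC libraries lie above the libraries of both other groups in each chain.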

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

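No test in this part was chosen after its result was seen. The genes examined were those named in the text, many of them named for their values here, so the share given by chance is approximate. T cell receptor repertoire measures and measures of each library were examined too. In groups of 4 libraries, 1 library was set apart when its gap to the nearest other was large beside the range of the group. Chance gives about 1 in 20 such groups, or 23.9 of the 478 examined, and 18 were found, 5 of them in AOAH 3, 4 in vehicle 1 and 3 each in AOAH 1, AOAH 2 and vehicle 4.

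The histone gene H4c12 stood at 13.58 TPM in vehicle 1 and 0 to 1.64 TPM in the other vehicle libraries. Vehicle 1 also stood apart in Cln8 (2.29 TPM, the others 4.06 to 4.18), which was named among the rises with AOAH, in Dgka (103.62 TPM, the others 100.0 to 100.38) and in the fatty acid oxidation gene Acadm (47.93 TPM, the others 41.42 to 42.36). Vehicle 4 did so in the cytokine Lif (22.5 TPM, the others 29.41 to 29.83), in Manf (519.68 TPM, the others 531.94 to 534.22) and in Suclg2 (34.74 TPM, the others 37.83 to 38.45). In AOAH 1 these were Socs3 (10.91 TPM, the others 9.82 to 9.95), Mdh2 (368.16 TPM, the others 372.84 to 373.23) and Trac (256.07 TPM, the others 271.48 to 274.51). In AOAH 2 they were Fam162a (197.16 TPM, the others 185.88 to 186.65), Idh3a (114.92 TPM, the others 107.05 to 107.98) and Tkt (365.75 TPM, the others 381.42 to 384.18). In AOAH 3 they were Cpt1a (14.18 TPM, the others 12.4 to 12.64), Isg15 (11.3 TPM, the others 9.27 to 9.61), Cxcl10 (10.01 TPM, the others 11.58 to 11.79), Trp53 (165.35 TPM, the others 155.14 to 156.21) and Suclg2 (37.72 TPM, the others 35.51 to 35.82).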

How the results depend on the processing

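The alternatives were planned except the omission of single libraries from the correlation of both treatments, which was chosen after seeing the data. With an estimated correlation 0 of the lists written beforehand were called for AOAH, 0 for PC and 0 for AOAH against PC. The preset correlation called 14, 21 and 17. That test estimates the correlation among members and has fewer degrees of freedom, and which of these ended the calls was not tested. Correlation does not account for each loss, because heat shock genes for PC (estimated correlation -0.0097) lost their call too. By contrast fry, which does not compare a list with other genes, called 28 for AOAH against PC. For the correlation of both treatments, divisions of the vehicle libraries gave -0.223, -0.216, -0.279, -0.235 and -0.214, since each treatment then had its own vehicle libraries, and omitting 1 library gave -0.0733 to 0.0178. Genes called for PC numbered 1339 with no filter, where more low genes were tested, and 1274 to 2083 with 1 library omitted. With batch as a block 2300 genes were called for AOAH, 1572 for PC and 4246 for AOAH against PC. Among genes covered by the rule the block ended 3 calls for AOAH (Il2ra, H2bc14 and Mdh2, the last with adjusted p = 0.0536), 9 for PC and 0 for AOAH against PC, and among lists that of the tricarboxylic acid cycle for AOAH. Of all genes named in the text, whether or not under the rule, it ended 15 of 161 calls for AOAH, 30 of 175 for PC and 16 of 198 for AOAH against PC. Outside the rule these included Ccl4, Gzma, H2-Aa, Osm, Pdlim1, Plaa, Tnfsf9, Trib3 and Xcl1 for AOAH, Acadm, Acadvl, Bax, Bbc3, Bcl2l1, Cflar, Cpt1a, Ctsw, Gadd45b, Hspa4, Junb, Lpcat1, Mboat7, Pcyt1a and Rel for PC, and Bcl2a1b, Ndufa2 and Polr1c for AOAH against PC. With no filter the PC calls of Il2, Nr4a1, Myc, Acsl1, Acaca, Bcl2a1b and Norad ended as well. Myc lost its PC call with TMM rescaling and quantile normalization, Acaca with vehicle 4 included and with 1 fit over all libraries, and H4c12 its call for AOAH against PC with a pseudocount of 0.1.

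Of the genes covered by the rule, 66 of 75 called for AOAH, 75 of 97 for PC and 85 of 87 for AOAH against PC held their call in every alternative, and no called gene changed direction. Genes that were not called crossed 0 in places. For AOAH, Gzmb went to 0.052 with quantile normalization, Tnf ranged from -0.0211 to 0.0938 and Ifng from -0.0563 to 0.0421 with 1 library omitted. For PC, Ifng was 0.0045 with 1 fit over all libraries, 0.0234 with quantile normalization and 0.0045 with vehicle 4 included, and with 1 library omitted Ifng ranged from -0.1338 to 0.0137 and Cd69 from -0.03 to 0.0983. For AOAH against PC, Pdcd1 was -0.0058 with the batch block, -0.0439 with quantile normalization and -0.0168 to 0.0179 with 1 library omitted, and Ifng was 0.0015 with TMM rescaling and -0.043 to 0.0166 with 1 library omitted. The difference in TRA clonotypes between AOAH and vehicle ranged from -66.5 to 24.5. For these shifts the cause was not tested. Depth per library is unknown, so its effect on low genes and on clonotype numbers was not measured.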

Other observations

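The tests of scaling, of other spleen cells, of dilution by cell division, both tests on clonotypes and the test of hypoxia-inducible factor targets were chosen only after their results or closely related values had been seen. Against the general opposition, 186 genes moved the same way with AOAH and PC, and the members named here were chosen after their values were seen. Higher under both were Lag3, at 40.5 TPM with AOAH, 40.4 TPM with PC and 26.1 TPM with vehicle, Cd200 (log2 changes 0.63 and 0.34), the phosphatase Dusp6 (0.38 and 0.61), the repressor Bhlhe40 (0.34 and 0.47) and the chemokine Ccl3 (0.38 and 0.43). Lower under both were Il10ra, of the inhibitory receptor list (-0.30 and -0.40), the interferon-inducible Isg15 (-0.39 and -0.44), Gimap7, a lymphocyte GTPase (-0.41 and -0.59), and Glrx, a glutaredoxin (-0.41 and -0.68). Ifngr1, a chain of the interferon gamma receptor, fell with AOAH (-0.73) and rose with PC (0.56), and Ccl5 (-0.92) and Gzma (-0.72) fell with AOAH.

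Lists closest to the chemistry of the treatments were not called. Phospholipid remodelling genes rose in 6 of 30 cases and fell in 1 with AOAH (adjusted p = 0.123), and rose in 3 and fell in 3 of 29 with PC (adjusted p = 0.409). With PC these were Pld3 (0.51), Chkb (0.33) and Mboat7 (0.17), higher, and Pcyt1a (-0.57), Mboat1 (-0.54) and Lpcat1 (-0.24), lower. Arachidonate and eicosanoid genes rose in 3 of 11 cases and fell in 1 with AOAH (adjusted p = 0.462), and rose in 1 and fell in 2 of 11 with PC (adjusted p = 0.945). The prostaglandin E2 receptor Ptger2 (0.53) was the one that rose with PC, and Lta4h (-0.28) and Ptges3 (-0.13) fell, while with AOAH Acsl4, Ptges3 and Plaa rose and the thromboxane receptor Tbxa2r fell (-0.57). The p53 and apoptosis list was not called with PC (5 of 27 higher, 4 lower, adjusted p = 0.512), though its members Cdkn1a, an inhibitor of the cell cycle (0.83), and the death genes Bbc3 (0.57), Pmaip1 (0.52) and Bax (0.16) rose, as did Trp53inp1 (0.56). Gadd45g (-0.43), Trp53 (-0.16) and Bcl2l1 (-0.15) were among those that fell.

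Cell division genes higher with AOAH and lower with PC were the first pattern weighed. Other scalings moved the median of all genes by 0.0166 at most on the log2 scale, which is small beside the list medians of 0.27 to 0.34 with AOAH and -0.47 to -1.04 with PC. Each of these scalings brings the libraries to a common level, so the values cover only the choice among them. They cannot show a change in total RNA per cell, and the spike-in RNA was not used here. In 6 of 6 divisions of the vehicle libraries the medians kept opposite directions, which decides nothing about odd vehicle libraries, since one shared by both comparisons would move both the same way. After a fit on GC content, transcript length and expression, which explained 3.62% of the variance, the median AOAH change of the 74 members was 0.294 against 0.313 before. A difference in how far or how many of the cells had divided at 24 h may lie behind the pattern, and no count of cells was used here.

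Interferon response genes lower with AOAH were the next pattern. After the same fit the median change of 40 members was -0.504 against -0.474 before, so GC content and length leave it in place. Lists of other spleen cells had 80 members outside the interferon list, of which 8 had over 8 TPM in vehicle: Ighm (145 TPM), Eomes (99.2), Cst3 (74.7), Ctss (69.2), Klrk1 (25.6), Cd74 (19.6), Batf3 (14.1) and Cd79b (8.10), after a kit isolation of CD8+ cells. With AOAH the members that fell lost 68.4 TPM in all (Ctss 18.3, Ighm 16.8 and Eomes 14.4 TPM the most), which is 6.71% (6.41% to 7.04% with 1 library omitted) of the 1019 TPM lost by the 37 interferon response genes that fell. Cells that had gone would take their own abundant transcripts along, so RNA carried away with them could account for little of the fall. This does not show that no B cells were lost, since IGL clonotypes averaged 2.50 with AOAH and 5.25 with vehicle. A signal from such cells to the T cells was not measured, so its loss is left open. Dilution of old RNA by cell division needs the interferon response genes to rise with PC by about as much as they fell with AOAH. The median PC change of the 37 genes that fell was -0.0148 beside -0.512 with AOAH. Its 95% interval of -0.0582 to 0.115 came from resampling genes, which are not independent, and holds no spread between libraries. The bound on the median had been set at 0.10, which the interval passes. It was read on the median only after the result was seen. Weaker interferon signalling with AOAH is a possible explanation, which these RNA values do not test.

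More clonotypes with PC were the last pattern. TRA clonotypes per TPM of Trac were 1.10 times as high with PC (4.32 to 4.57) as with vehicle 1 to 3 (3.73 to 4.33), where clonotypes were 1.47 times as many. For TRB these were 1.11 times as high (2.42 to 2.67 against 2.14 to 2.48), and in each chain 2 of 3 PC libraries lay above vehicle 1 to 3, though below vehicle 4 (4.63 and 2.74). More receptor RNA may therefore account for part of the difference, and whether it accounts for the rest is open. Reads per library are not in the tables used here, and vehicle 4 alone had 1.18 times the TRA clonotypes of vehicle 1 to 3 with 1.03 times their Trac, so deeper sequencing cannot be told apart from it. A more diverse population of cells was not tested.

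Grouping the libraries in other ways gave far fewer calls. For AOAH against vehicle only 1 of 35 groupings of the 8 libraries, the real one, called as many as 2913 genes, and the highest other called 4. That share is under 0.05. It counts against chance only if libraries are exchangeable across batches and came from separate animals or cultures, which the labels do not say. For AOAH against PC 1 of 35 groupings of the 7 libraries, the real one, called 5307, and the highest other called 5, with the same conditions on its reading. For PC against vehicle 1 of 10 groupings called 2270 and the highest other 4, and 10 groupings are too few for a share under 0.05. These counts move libraries across batches. Of groupings that part every same-batch pair there are 8 for AOAH against vehicle (highest other 3 genes) and 8 for AOAH against PC (highest other 1 gene), and 8 are too few for a share under 0.05.

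Because Slc16a3, Ak4, Ldha and other glycolysis genes rose with AOAH, targets of hypoxia-inducible factor outside glycolysis were tested as a hypothesis. Among 17 members not seen before, the median log2 change was 0.103, with 6 higher (Ankrd37, Ero1a, Fam162a, Jmjd6, Mif and P4ha1) and none lower. These members missed the threshold once adjusted over the 6 tests of both added lists (adjusted p = 0.0615, and adjusted p = 0.105 with an estimated correlation), and they had adjusted p = 0.901 with PC, so a modest rise of these targets may be there and was not shown. Because Il7r, Klf2 and S1pr1, all targets of FOXO transcription factors, fell with AOAH, 22 other FOXO targets were tested, of which 13 fell and 1 rose. Their median was -0.451 (adjusted p = 9.22e-07, and adjusted p = 0.00804 with an estimated correlation). With PC 9 of the 22 rose and none fell, with a median of 0.17 (adjusted p = 1.98e-04, and adjusted p = 0.105 with an estimated correlation). Lower FOXO activity with AOAH may account for part of the fall of naive-cell genes, a hypothesis found and tested in the same libraries.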
